A study of Phytophthora sojae with 12 samples.

How the data were processed

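The data were 12 Affymetrix soybean arrays, hybridised with biotin-labelled cRNA made from total RNA with an oligo(dT) primer, per the labels' protocols. The deposited values were on the log2 scale, 1 value per probe set and array, and were made with GCRMA, which corrects background by probe sequence, normalizes between arrays and summarises probes, per the submitters' processing notes. The version and settings of GCRMA, and whether the soybean probe sets were normalized together with those of *P. sojae*, are not given in the sources used here. The table held 15869 rows. Of these, 15820 had IDs that start with PsAffx and were tested, and 44 ribosomal RNA rows, 4 *P. sojae* actin control rows and 1 row with a soybean ID prefix were fitted apart. Because GCRMA normalizes between arrays, and infected tissue holds plant RNA that mycelium does not, a difference between 0 h and infected arrays can come from the mixture of RNA as well as from the transcript itself.

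Groups came from the time in the labels: 0 h mycelium and infected tissue at 3, 6 and 12 h, with 3 arrays each. The labels give replicate numbers 1 to 3 in every group and say that the experiment was done 3 times, without saying whether a number marks a shared run. No depth applies to arrays, and their number limits the precision. No scanner files were used here, so signal over background could not be checked per spot.

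Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 12 arrays), with a residual df of 8 and a prior df of 1.72. The fit takes 1 spread per probe set for all 4 groups, but the groups differed. The median SD was 0.19 at 0 h, 0.070 at 3 h and 0.094 at 12 h, and 0.16, 0.24 and 0.27 in the brightest 10% by mean. Where the 0 h spread is the larger, the SE can be too small against 0 h and too large between infected times. The 6 contrasts were each time against 0 h and the infected times against each other. P-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05, and calls of at least 2-fold (log2 change of 1) were also counted. A moderated F test over the contrasts against 0 h asked which probe sets differed between times. With 3 arrays against 3 an exact test on a single probe set cannot go below p = 0.1, which is why limma's pooled spread was used. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 10 lists and 6 contrasts together (60 tests), and with an estimated correlation. Log2 changes are given with their limma SE and levels as mean ± SD of 3 arrays.

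Of 32 keyword lists fixed before the data were examined, 30 matched no row because the table holds IDs and no gene titles. The list of RXLR effectors matched 13 probe sets by the names Avr and Avh in the IDs, and the list of tubulin and actin matched the 4 actin control rows, which were too few to test and were used as an RNA quality measure. The lists of host markers for photosynthesis and plant defence were among the 30. ID prefixes with at least 30 probe sets made 9 more lists. In the reference table of *P. sojae* V3.0 genes, 0 locus tags occur as IDs, and the symbols of 6 genes do, all of them effectors already named by their IDs. The rule for named genes, also fixed before, asked for the largest changes among probe sets with an informative gene name, and, with no annotation, for the 2 probe sets with the largest rise and the 2 with the largest fall per contrast among those past the threshold and separated in all 3 arrays. The genes fixed by name beforehand were kept whether or not they passed; of these Avr1b and actin were found. The other probe sets named in their IDs were added.

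The alternatives fixed before the data were examined were a replicate block, median centring, a second quantile normalization, the brighter probe sets by mean (those above the median), a mean log2 value above 6, eBayes with trend and robust settings, array weights, a fit to the 6 arrays compared, a minimum log2 change of 0.5 with treat, a floor at log2 4, leaving out each array in turn, fry and an estimated correlation. Cyclic loess, the actin 5′ minus 3′ difference as a covariate, leaving out infected replicate 1 or infected replicates 2 and 3, and lists matched on mean level were added after the data had been seen. Centring on ribosomal proteins was not run because no probe set is annotated as one.

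The procedure was tried on simulated data with 200 of the 15820 probe sets changed. For 3 h against 0 h, 34.7%, 68.7% and 96.6% of simulated log2 changes of 0.5, 1 and 2 were recovered, and 7.25% of the calls were false. For 6 h against 3 h the shares were 32.4%, 65.2% and 98.3%, with 5.26% false, and for 12 h against 3 h 34.9%, 64.3% and 91.0%, with 4.48% false. The contrasts against 0 h called far more probe sets, 11254 at 3 h. The adjusted threshold depends on the share changed, so these rates may not hold for those contrasts. A shift of 0.5 planted in the psZO list at 12 h was called in the 3 contrasts that involve it, and 0 other lists were called. Chance values for overlaps came from 20 simulations of unchanged groups.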

Results

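The expression of *Phytophthora sojae* genes was measured with the Affymetrix soybean array, which carries probe sets for this oomycete pathogen beside those of its host. Strain P6954 was grown in V8 liquid medium at 25 °C for 2 days and washed, and the mycelium was placed in a slit of about 1 cm cut in hypocotyls of 9-day-old seedlings of the susceptible soybean cultivar Sloan. Tissue around the slit was taken after 3, 6 and 12 h, and washed mycelium that never met a plant was the 0 h control. Each of the 4 groups had 3 arrays, and the labels describe 3 repeats of the whole experiment. The values were 15820 *P. sojae* probe sets on the log2 scale, and precision was limited by the 3 arrays per group. The median signal was 4.16 to 4.17 on the 0 h arrays, 4.40 to 4.45 on the 3 h and 6 h arrays and 4.21 to 4.28 on the 12 h arrays, and the 90th percentile was 7.80 to 7.86, 6.84 to 6.99 and 7.20 to 7.30. Pearson correlations across probe sets, which are not independent replicates, were 0.967 to 0.985 between arrays of a group, 0.947 to 0.970 between infected arrays of different times and 0.829 to 0.889 between 0 h and infected arrays. The *P. sojae* actin control, read by probe sets at both ends of the transcript, had a 5′ signal below its 3′ signal by a log2 difference of -1.93 to -1.65 on the 0 h arrays and of -2.08 to -1.52 on the infected replicate 1 arrays. On the 6 infected arrays of replicates 2 and 3 this difference was -6.87 to -3.38.

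**Figure D1:**
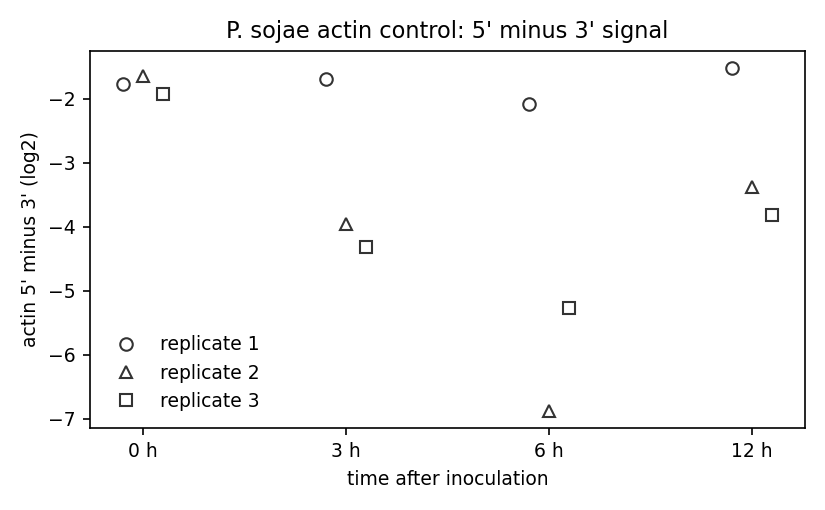
The 5′ minus 3′ log2 signal of the *P. sojae* actin control is plotted for each of the 12 arrays, by hours after inoculation, with a symbol per replicate number. Infected replicates 2 and 3 lie between -6.87 and -3.38, below all 0 h and infected replicate 1 arrays, which lie between -2.08 and -1.52.

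The probe set IDs name 19 probe sets after a gene or gene family, and the files do not pair the other IDs with genes. Of these, 13 carry the names Avr1b or Avh1b, given to members of the RXLR effector family. RXLR effectors are proteins that *Phytophthora* species deliver into plant cells, and Avr1b-1 is the effector recognised by soybean plants with the resistance gene Rps1b. The remaining names are HisK-2 and 7TMS-1 to 7TMS-5. The Avr1b-1, Avh1b-7a, 7TMS-1 and 7TMS-5 probe sets are of the type that can match several transcripts, so their values may combine related genes.

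Tissue at 3 h was compared with 0 h mycelium to find genes that differed early in infection. Of the 13 effector probe sets, 12 rose, 0 fell and 1, Avr1b-1, did not pass the test, and the count adjusted over the list alone was also 12. Their median log2 change was 1.24, against 0.21 over all probe sets. Avh1b-14 rose from 2.94 ± 0.044 (SD, n = 3) to 5.12 ± 0.56, a log2 change of 2.18 ± 0.23 (SE, adjusted p = 2.48e-05) that was 1.12 (adjusted p = 0.00579) with values under 4 raised to 4. Avh1b-15 rose from 3.92 ± 0.33 to 5.96 ± 0.062, or 4.12-fold, and Avr1b-8 rose from 5.62 ± 0.26 to 7.60 ± 0.054, or 3.93-fold. Avr1b-1 stood at 6.84 ± 0.17 at 0 h and 6.20 ± 0.40 at 3 h, a difference of -0.64 ± 0.42 (SE, adjusted p = 0.197). All 3 arrays at 3 h lay below all 3 at 0 h. The SE pools the spread of all times, and the SD was 0.97 at 12 h. With 12 h replicate 1 alone left out, the same difference passed downwards by limma (adjusted p = 0.0391). Without the infected replicate 1 arrays this difference was -0.84 (adjusted p = 0.0141), and it had the other sign after quantile normalization (0.058, adjusted p = 0.926) and cyclic loess (0.20, adjusted p = 0.737). As a list the effectors were higher relative to other probe sets by camera with the preset correlation (adjusted p = 0.000725). That call was lost with an estimated correlation (adjusted p = 0.144). The list's median exceeded all of 10000 random lists matched on mean level (percentile 100). These lists draw probe sets independently and so, unlike the estimated correlation, ignore that members can vary together. After cyclic loess, which removes a trend of differences with level, 11 of the 13 passed the test upwards. Without the infected replicate 2 and 3 arrays, whose actin 5′ signal lay further below the 3′ signal, 10 of the 13 did. That fit held 1 array per infected time, taken to vary like the 0 h arrays. With values under 4 raised to 4, 10 passed upwards and the median was 0.65. Of the 13, 10 had a 0 h mean under 4, where signal over background was not checked. Avh1b-17 and Avh1b-20 lay under 4 on all 12 arrays. Only 6 of the 13 were among the brighter probe sets, and 5 of these passed upwards when those alone were tested. Only 3 had a mean above 6, and 2 of these passed upwards in that fit.

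**Figure D2:**
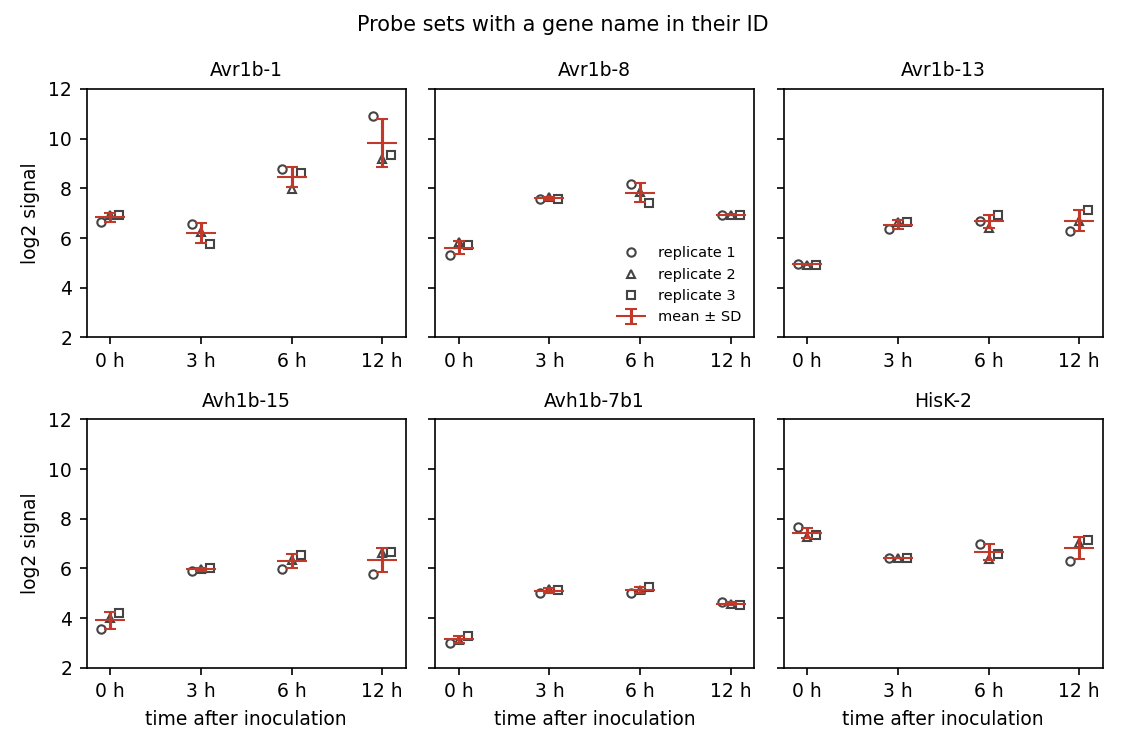
The log2 signal of 6 probe sets named in their IDs is plotted per array by hours after inoculation, with a symbol per replicate number and red bars for the mean ± SD of 3 arrays. Avr1b-1 means were 6.84, 6.20, 8.45 and 9.82 over the 4 times, while the other 4 effectors shown were already higher at 3 h than at 0 h, and HisK-2 was lower at 3 h, at 6.42 against 7.42.

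HisK-2 fell from 7.42 ± 0.20 to 6.42 ± 0.0032 at 3 h (adjusted p = 0.00252), but its log2 change was -0.19 (adjusted p = 0.48) after quantile normalization and -0.35 (adjusted p = 0.179) after cyclic loess. 7TMS-3 rose by 1.33 ± 0.16 (SE, adjusted p = 6.09e-05), and the change was also 1.33 without infected replicates 2 and 3. The infected groups have 1 array each in that fit, so its spread comes from the 0 h arrays alone. For 7TMS-3 the SD was 0.41 at 0 h, against 0.052 at 3 h, so the SE of 0.16 may be too small. The 7TMS-4 change was 0.44 ± 0.10 (SE, adjusted p = 0.00309), with 0.19 (adjusted p = 0.127) after median centring. 7TMS-1, 7TMS-2 and 7TMS-5 did not pass the test, although 7TMS-5 did downwards after median centring (-0.19, adjusted p = 0.0271) and cyclic loess (-0.25, adjusted p = 0.00781) and upwards without 0 h replicate 2 (0.12, adjusted p = 0.0407). Probe sets that share one of 9 ID prefixes, whose meaning the sources used here do not give, were tested as lists. Members with the prefix psML were 15 up, 40 down and 26 not passing, 14 up and 39 down adjusted over the list alone, with a median of -0.60 (camera adjusted p = 6.61e-06; adjusted p = 0.00342 with an estimated correlation). Members with psMC were 19 up and 78 down of 151, and the same numbers adjusted over the list alone, with a median of -0.54 (adjusted p = 6.24e-07; adjusted p = 0.0344 with an estimated correlation and 0.0931 after quantile normalization). The psMY list (17 up and 29 down of 70, and the same adjusted over the list alone) was lower by camera (adjusted p = 0.00813; adjusted p = 0.029 with an estimated correlation), and the call was lost after cyclic loess (adjusted p = 0.393). The psZG list (11 up and 24 down of 72, 11 and 23 adjusted over the list alone) was lower by camera (adjusted p = 0.00745), a call lost with an estimated correlation (adjusted p = 0.154) and after cyclic loess (adjusted p = 0.661). Among random lists matched on mean level, the medians of psMY and psZG lay at percentiles 11.67 and 9.77, and those of psML and psMC at 0 and 0.31. The psHA, psHB, psMA, psZO and psZS lists did not pass.

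At 3 h 11254 of the 15820 probe sets differed from 0 h mycelium by limma at an adjusted p of 0.05, with 7138 higher and 4116 lower. Of these, 1883 were at least 2-fold higher and 2616 at least 2-fold lower. All 3 arrays of one group lay beyond all 3 of the other for 76.8% of the probe sets, against 10% by chance. Here and below, the 10% holds for a single probe set. Probe sets of an array can shift together, so the share over probe sets is not a test. The direction followed the signal level. In the brightest 10% by mean over all 12 arrays, 905 of 1582 probe sets were lower and 109 higher, with a median log2 change of -0.76, and in the dimmest 10%, 1124 were higher and 93 lower, with a median of 0.30. Probe sets named CL with a contig number, whose median 0 h level was 7.81, were lower in 1156 of 1899 cases and higher in 166. Those named C with a number, whose median 0 h level was 3.83, were higher in 6373 of 12261 cases and lower in 2452. The 2 unnamed probe sets with the largest rise were psHA006iH10r_s_at, from 2.71 ± 0.10 to 13.35 ± 0.36, and psHB012xE14f_s_at, from 3.78 ± 0.56 to 14.33 ± 0.058. Those with the largest fall were CL2019Contig1_s_at, from 9.00 ± 0.34 to 3.51 ± 0.10, and CL75Contig1_at, from 9.79 ± 0.29 to 4.31 ± 0.48. The 2 with the largest rise are among the early risers described further below, which may read soybean transcripts in place of those of *P. sojae*. The share of calls that were higher was 63.4%, and it was 45.3% with each array centred on its median, 50.8% after cyclic loess and 46.5% with values under 4 raised to 4.

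**Figure D3:**
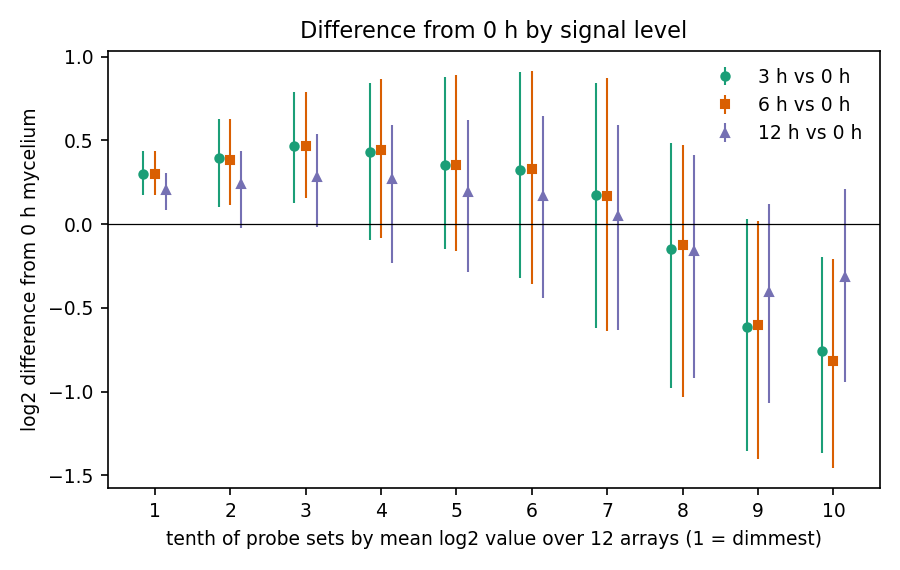
The median log2 difference from 0 h mycelium is plotted for each of 10 equal groups of the 15820 probe sets, ordered by mean log2 value over the 12 arrays, for the 3 infected times, with bars from the lower to the upper quartile over probe sets. The medians lie above 0 in the dimmer groups and below 0 in the 3 brightest, at -0.76, -0.82 and -0.31 in the brightest 10% at 3, 6 and 12 h.

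At 6 h all 13 effector probe sets were higher than in 0 h mycelium, 13 also when adjusted over the list alone, with a median log2 change of 1.45 against 0.22 over all probe sets. Avr1b-1 rose from 6.84 ± 0.17 to 8.45 ± 0.41 (SD, n = 3), or 3.06-fold, a log2 change of 1.62 ± 0.42 (SE, adjusted p = 0.00642), although it did not pass with array weights (1.55, adjusted p = 0.0669). The size of this change depended on the scaling, at 2.52 after quantile normalization and 2.47 after cyclic loess. Avh1b-15 was 5.18-fold and Avr1b-8 4.63-fold higher, with log2 changes of 2.37 ± 0.25 (SE, adjusted p = 2.03e-05) and 2.21 ± 0.18 (SE, adjusted p = 4e-06). The list was higher by camera (adjusted p = 0.000186), a call lost with an estimated correlation (adjusted p = 0.12). After cyclic loess, and also without the infected replicate 2 and 3 arrays, 12 of the 13 passed upwards. With values under 4 raised to 4, 11 did and the median was 0.72. All 6 effectors among the brighter probe sets passed upwards when those alone were tested, as did all 3 with a mean above 6. HisK-2 fell by 0.77 on the log2 scale (adjusted p = 0.0101), but its difference was 0.090, in the other direction, after quantile normalization (adjusted p = 0.737). 7TMS-3 rose by 1.31 ± 0.16 (SE, adjusted p = 6.73e-05), and the change without infected replicates 2 and 3 was 1.30 (adjusted p = 0.0656). The 7TMS-4 change of 0.40 (adjusted p = 0.00532) became -0.024 (adjusted p = 0.86) after quantile normalization. The psML and psMC lists were again lower, with medians of -0.67 and -0.54. Of psML members 15 rose and 41 fell, the same numbers as adjusted over the list alone, and of psMC members 20 rose and 77 fell, 18 and 77 adjusted over the list alone. Their camera adjusted p-values were 6.61e-06 and 6.24e-07, and 0.00342 and 0.0344 as adjusted p with an estimated correlation. The psMY list was lower (17 up and 33 down of 70, also adjusted over the list alone; adjusted p = 0.00554, and adjusted p = 0.029 with an estimated correlation). The psMA and psZG lists were lower with the preset correlation (adjusted p = 0.0387 and 0.00745), and both calls were lost with an estimated correlation (adjusted p = 0.154 for each). For psMA 105 members rose and 101 fell of 299, also adjusted over the list alone, and for psZG 13 rose and 24 fell, 12 and 24 adjusted over the list alone. The psMY, psMA and psZG calls were also lost after cyclic loess (adjusted p = 0.305, 0.267 and 0.661).

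In all, 11430 probe sets differed between 6 h and 0 h, 7259 higher and 4171 lower, with 1920 at least 2-fold higher and 2717 at least 2-fold lower. The share separated by group was 76.0%, against 10% by chance. The largest rises were again those of psHA006iH10r_s_at, to 12.77 ± 0.57, and psHB012xE14f_s_at, to 13.58 ± 0.27. CL392Contig1_at fell from 10.67 ± 0.093 to 4.08 ± 0.61 and psHA006iC08r_at from 10.52 ± 0.36 to 4.45 ± 1.47. In the brightest 10% 946 of 1582 probe sets were lower. The share of calls that were higher was 63.5%, and 44.9% after median centring, 50.6% after cyclic loess and 46.3% with values under 4 raised to 4.

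At 12 h all 13 effector probe sets were higher than in 0 h mycelium, 13 also adjusted over the list alone, with a median log2 change of 1.14 against 0.13 over all probe sets. Avr1b-1 reached 9.82 ± 0.97 (SD, n = 3), 7.88-fold above 0 h, a log2 change of 2.98 ± 0.42 (SE, adjusted p = 0.000241). The change was 4.09 from the infected replicate 1 array alone and 2.42 from replicates 2 and 3. Avh1b-15 was 5.41-fold and Avr1b-13 3.39-fold higher, with log2 changes of 2.44 ± 0.25 (SE, adjusted p = 2.62e-05) and 1.76 ± 0.20 (SE, adjusted p = 6.04e-05). The list was higher by camera (adjusted p = 3.63e-05), a call lost with an estimated correlation (adjusted p = 0.0952). The 6 effectors among the brighter probe sets all passed upwards when those alone were tested, as did the 3 with a mean above 6. With values under 4 raised to 4, 8 of the 13 passed upwards and the median was 0.37, and 12 passed after cyclic loess. Without the infected replicate 2 and 3 arrays 11 did. The HisK-2 change was -0.61 ± 0.22 (SE, adjusted p = 0.0375), -0.031 (adjusted p = 0.918) after quantile normalization and -0.096 (adjusted p = 0.724) after cyclic loess. With the replicate block it no longer passed (adjusted p = 0.0623). 7TMS-3 rose by 1.10 ± 0.16 (SE, adjusted p = 0.000319), with a change of 0.99 (adjusted p = 0.133) without infected replicates 2 and 3, and the 7TMS-4 change was 0.30 ± 0.10 (SE, adjusted p = 0.0275), 0.079 (adjusted p = 0.553) after cyclic loess. Of psML members 8 rose and 37 fell (8 and 36 adjusted over the list alone; camera adjusted p = 6.61e-06; adjusted p = 0.00342 with an estimated correlation). Of psMC members 17 rose and 67 fell (17 and 65 adjusted over the list alone; adjusted p = 6.05e-06), a call lost with an estimated correlation (adjusted p = 0.0551). The psMY list was lower with 14 up and 29 down, also adjusted over the list alone (adjusted p = 0.00898, and adjusted p = 0.029 with an estimated correlation). The psMA list was lower with 60 up and 85 down, 59 and 80 adjusted over the list alone (adjusted p = 0.00949), which was lost with an estimated correlation (adjusted p = 0.113). After cyclic loess psMY and psMA no longer passed (adjusted p = 0.363 and 0.12).

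Between 12 h and 0 h 9500 probe sets differed, 5798 higher and 3702 lower, with 1109 at least 2-fold higher and 2271 at least 2-fold lower. The share separated by group was 67.7%, against 10% by chance. psHA006iH10r_s_at and psHB012xE14f_s_at had the largest rises, to 12.51 ± 0.73 and 12.39 ± 0.35. CL392Contig1_at fell to 4.34 ± 0.13, and CL1036Contig1_at fell to 5.13 ± 0.20, a log2 change of -5.87. The brightest 10% had 571 of 1582 probe sets lower and 212 higher. Of all calls 61.0% were higher, against 52.4% after median centring, 52.1% after cyclic loess, 40.0% with values under 4 raised to 4 and 41.3% when the brighter probe sets alone were tested.

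Many probe sets changed the same way at more than one time. At 3 h and 6 h 6804 were higher at both and 3819 lower at both, where independent lists of those sizes would share 3275 and 1085. The 3 h and 12 h lists shared 5414 and 3294 (independent 2616 and 963), and the 6 h and 12 h lists 5465 and 3334 (independent 2660 and 976). Simulated unchanged groups, with shared 0 h arrays that were simulated too, shared 0. With nothing changed almost no probe set is called, so this 0 is no yardstick for the shared counts. The correlation of log2 changes across probe sets was 0.957, 0.887 and 0.914 for the 3 pairs, against 0.499 to 0.503 in the simulation, and the covariance was 1.16, 0.94 and 1.00, against 0.027, 0.027 and 0.026. The 3 controls were too few to be split, so part of these overlaps may come from the shared 0 h arrays. For random spread alone, taken as equal at all times, the simulated covariance puts that part as small. All 3 contrasts also set tissue that holds plant RNA against mycelium that does not. This shared difference in the mixture of RNA can itself give overlap above that of independent lists. Its part was not measured, so the overlap does not show a lasting response of the pathogen.

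The infected times were then compared with each other, with plant tissue on both sides. Between 6 h and 3 h 0 of the 13 effectors passed by limma, 1 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. Avr1b-1 stood at 6.20 ± 0.40 (SD, n = 3) at 3 h and 8.45 ± 0.41 at 6 h, a difference of 2.26 ± 0.42 (SE, adjusted p = 0.0544) with all 3 arrays higher at 6 h. Its adjusted p was 0.0192 when the brighter probe sets alone were tested, 0.00814 with a mean above 6, 0.0119 with the actin difference as a covariate and 0.0419 with array weights. It did not pass with the replicate block (adjusted p = 0.0559), median centring (0.0566), quantile normalization (0.0634), cyclic loess (0.085) or values under 4 raised to 4 (0.127). With single arrays left out it passed only without 12 h replicate 1 (0.0053), and its adjusted p reached 0.189 without 3 h replicate 3. Camera called 0 of 10 lists, of which 0 had an unadjusted p under 0.05, and fry also called 0. In all 99 probe sets differed, 33 higher and 66 lower at 6 h, and 853 had an unadjusted p under 0.05. C111000034_at rose from 7.97 ± 0.66 to 12.17 ± 0.33 and C395000001_at from 3.10 ± 0.98 to 6.77 ± 0.85. C78000056_at fell from 8.19 ± 0.35 to 4.50 ± 1.03 and CL214Contig2_at from 10.42 ± 0.44 to 7.04 ± 0.75. A fit to these 6 arrays alone called 4, and the share separated by group was 9.32%, against 10% by chance.

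Between 12 h and 6 h 4 effectors fell, 0 rose and 9 did not pass, with 1 up and 6 down adjusted over the list alone. Avr1b-8 fell from 7.83 ± 0.39 to 6.94 ± 0.017 (SD, n = 3), a log2 change of -0.90 ± 0.18 (SE, adjusted p = 0.0186), which did not pass after median centring (-0.72, adjusted p = 0.0579). Avh1b-7b1 fell by 0.56 on the log2 scale (adjusted p = 0.0103), with -0.37 (adjusted p = 0.0723) after cyclic loess. Avh1b-19 and Avh1b-7a fell by 0.56 and 0.28 (adjusted p = 0.0308 and 0.0376), and neither passed after median centring (adjusted p = 0.119 and 0.366). As a list the effectors did not pass (adjusted p = 0.0879). Avr1b-1 had a difference of 1.36 ± 0.42 (SE, adjusted p = 0.0759). This was 0.81 without 12 h replicate 1 and 0.72 (adjusted p = 0.478) after quantile normalization, and it passed with array weights (adjusted p = 0.0412) and among probe sets with a mean above 6 (adjusted p = 0.0415). The psZG list was higher at 12 h, with a median of 0.17, 4 members up and 0 down, also adjusted over the list alone (camera adjusted p = 8.65e-07; adjusted p = 0.029 with an estimated correlation and 0.00106 after cyclic loess). Camera also placed psMC and psML higher relative to other probe sets (adjusted p = 0.000725 and 0.00295), while their medians were -0.028 and -0.050 and their means 0.11 and 0.15. With an estimated correlation the psMC call was lost (adjusted p = 0.139) and that of psML held (adjusted p = 0.0281), and both were lost after cyclic loess (adjusted p = 0.537 and 0.181). Of psMC members 8 rose and 3 fell, 7 and 2 adjusted over the list alone, and of psML members 8 rose and 2 fell, 8 and 3 adjusted over the list alone.

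In all 1274 probe sets differed between 12 h and 6 h, 506 higher and 768 lower, but 360 were at least 2-fold higher and 29 at least 2-fold lower. The share separated by group was 64.1%, against 10% by chance for a single probe set. Every 12 h array had a lower median signal than every 6 h array, and this shift of whole arrays, which adds to the share, was not removed. In the brightest 10% 281 rose and 21 fell, and in the dimmer 5 of 10 such groups the median change lay between -0.19 and -0.098. The share of calls that were higher was 39.7%, against 85.7% after median centring (669 up, 112 down) and 62.4% after cyclic loess (211 up, 127 down). C136000046_at rose from 6.48 ± 0.17 to 10.88 ± 1.16 and CL1828Contig1_at from 4.82 ± 0.0070 to 9.14 ± 0.87. C111000034_at fell to 9.53 ± 1.48 and CL2553Contig1_at from 9.67 ± 0.50 to 7.41 ± 0.70. The count was 523 without 6 h replicate 2, 412 without 12 h replicate 2 and 593 without 12 h replicate 3. Without all infected replicate 2 and 3 arrays, limma called 0, with 1817 at an unadjusted p under 0.05.

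From 3 h to 12 h Avr1b-1 rose 12.3-fold, a log2 change of 3.62 ± 0.42 (SE, adjusted p = 0.00152). The change was 3.26 without the infected replicate 1 arrays and 4.34 without replicates 2 and 3, where 1 array was set against 1. Of the other effectors 4 fell and 8 did not pass, and adjusted over the list alone 8 fell and 0 rose beside Avr1b-1. Those that fell were Avr1b-8 (-0.66, adjusted p = 0.0456), Avh1b-7b1 (-0.52, adjusted p = 0.0101), Avh1b-7a (-0.29, adjusted p = 0.0303) and Avh1b-20 (-0.26, adjusted p = 0.0357). With the replicate block Avh1b-7b1 alone passed downwards. After median centring, and also after cyclic loess, 0 of the effectors passed downwards, with changes of these 4 that stayed below 0. The list did not pass (adjusted p = 0.336), and its median of -0.27 and mean of 0.035 differed in sign. The psZG list was higher with 8 members up and 0 down, 9 and 0 adjusted over the list alone, and a median of 0.13 (camera adjusted p = 8.65e-07; adjusted p = 0.029 with an estimated correlation and 0.00135 after cyclic loess). The psMC and psML lists were placed higher by camera (adjusted p = 0.000785 and 0.00488), with medians of -0.030 and -0.029. With an estimated correlation their adjusted p-values were 0.139 and 0.029, and both calls were lost after cyclic loess (adjusted p = 0.537 and 0.305). Of psMC members 12 rose and 6 fell and of psML members 5 rose and 3 fell, or 12 and 6 and 5 and 2 adjusted over the list alone.

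In all 1646 probe sets differed between 12 h and 3 h, 577 higher and 1069 lower, with 389 at least 2-fold higher and 92 at least 2-fold lower. The share separated by group was 66.0%, against 10% by chance for a single probe set. Every 12 h array also had a lower median signal than every 3 h array, a shift of whole arrays that adds to the share. C119000001_at rose from 4.49 ± 0.24 to 9.90 ± 0.72 and C5000065_at from 5.31 ± 0.69 to 10.65 ± 0.67. psHB023xD24f_at fell from 9.27 ± 0.23 to 5.99 ± 0.38 and psHB014xG23f_at from 10.25 ± 0.29 to 7.02 ± 0.087. These falling probe sets are also among the early risers described below, which may read soybean transcripts. The share of calls that were higher was 35.1%, against 80.1% after median centring (698 up, 173 down) and 55.7% after cyclic loess (325 up, 259 down). The count was 938 without 3 h replicate 2, 698 without 3 h replicate 3, 663 without 12 h replicate 2 and 805 without 12 h replicate 3.

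Over all 4 times, limma's moderated F test found 11261 of the 15820 probe sets to differ between times. Their group mean was highest at 0 h for 3885, at 3 h for 3684, at 6 h for 3018 and at 12 h for 674. It was lowest at 0 h for 6860, at 3 h for 1194, at 6 h for 1360 and at 12 h for 1847. Among the 2192 called probe sets in the 2 brightest of these groups, 1543 were highest at 0 h, 146 at 3 h, 108 at 6 h and 395 at 12 h.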

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

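The contrasts between infected times were fixed before the data were examined, while the levels of the ribosomal RNA rows and the cyclic loess values were looked at only after the results were seen. Of the probe sets named in their IDs, 9 differences between infected times stood out because limma's test of the difference itself passed. Avr1b-1 was higher at 12 h than at 3 h by 3.62 (adjusted p = 0.00152) and by 3.31 (adjusted p = 0.0041) after cyclic loess. Avr1b-8 at 12 h differed by -0.90 from 6 h and by -0.66 from 3 h. The corresponding differences were -0.56 and -0.52 for Avh1b-7b1 and -0.28 and -0.29 for Avh1b-7a. Avh1b-19 had -0.56 against 6 h and Avh1b-20 -0.26 against 3 h. After cyclic loess Avr1b-8 against 6 h alone of these 8 falls passed (-1.09, adjusted p = 0.0341), and Avh1b-7a, for example, was -0.090 against 6 h (adjusted p = 0.504). The adjusted p-values of the falls ranged from 0.0101 to 0.0456. With the replicate block 4 of these 8 falls no longer passed: Avr1b-8 (adjusted p = 0.0702), Avh1b-7a (adjusted p = 0.0617) and Avh1b-20 (adjusted p = 0.0547) against 3 h and Avh1b-7a against 6 h (adjusted p = 0.0738). The block leaves these log2 differences as they were and changes only the spread and the residual df of the fit.

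The ribosomal RNA rows were outside the main measurement, and 7 of the 44 had every infected array above every 0 h array by more than 1 log2 unit. The gap between the lowest infected and the highest 0 h array was 6.36 for rRNA_931_RC, 5.83 for rRNA_852, 2.62 for rRNA_931, 2.42 for rRNA_852_RC, 2.27 for rRNA_177_RC, 1.79 for rRNA_1500 and 1.36 for rRNA_222_RC. By limma over the 49 rows fitted apart, 16 of the 44 rose and 4 fell at 3 h, 20 rose and 2 fell at 6 h, and 13 rose and 0 fell at 12 h, with 18 at an unadjusted p under 0.05 at 12 h. Between infected times 0 passed, with 6, 10 and 2 at an unadjusted p under 0.05 for 6 h against 3 h, 12 h against 6 h and 12 h against 3 h.

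Other splits of the arrays were counted for each comparison. The 6 arrays of 2 groups allow 10 splits into 3 and 3, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave the largest count in a fit to those arrays. It was 10968 for 3 h, 10710 for 6 h and 8423 for 12 h against 0 h, with 0 as the highest of the other splits. For 6 h against 3 h it was 4 against a highest other of 2, for 12 h against 6 h 1587 against 0, and for 12 h against 3 h 2923 against 0. For the F test, 1 of 100 splits of the 12 arrays into 4 groups, the real one, gave a count as large, the smallest share that 100 splits can give. The real count was 11261. The highest of the other splits reached 9402, so the size of the count alone says little about the times.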

How the results depend on the processing

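Cyclic loess, the actin covariate and leaving out infected replicate numbers were chosen after the data had been seen. Counts of changed probe sets stayed within 1.5 times the reported ones with the replicate block, trend and robust settings and the actin covariate. Where no cause is named below, the cause was not tested. Centring on ribosomal proteins was not run, and treat was not run for the F test or single probe sets. Signal over background limits the dim probe sets: among those below the median of mean level, 58.6% had a range under 0.2 over the 6 arrays at 3 h and 6 h, so small differences there can pass.

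Against 0 h, the counts at 3, 6 and 12 h fell where fewer probe sets were tested, to 5082, 5168 and 4272 among the brighter probe sets and 1820, 1885 and 1413 among those with a mean above 6. They were 4918, 4980 and 3216 for a minimum log2 change of 0.5, 6295, 6461 and 4718 with values under 4 raised to 4, and 5044, 5403 and 3571 without infected replicates 2 and 3, where each lone infected array was assumed to vary like the 0 h arrays. With each array left out in turn they ranged from 10359 to 11257, 10623 to 11426 and 8223 to 9495. Between 6 h and 3 h the count was 166 with a mean above 6, 30 with the minimum change, 4 in the fit to 6 arrays and 0 without infected replicates 2 and 3 (1319 at an unadjusted p under 0.05 by limma), and 72 to 114 with single arrays left out. Between 12 h and 6 h it was 781 after median centring, 534 after quantile normalization, 338 after cyclic loess, 569 with a mean above 6, 3520 with array weights, 44 with the minimum change, 562 without infected replicate 1 and 0 without replicates 2 and 3 (1817 at an unadjusted p under 0.05). It ranged from 412 (without 12 h replicate 2) to 1773 with single arrays left out, and was 523 without 6 h replicate 2 and 593 without 12 h replicate 3. Between 12 h and 3 h it was 871, 827 and 584 after these scalings, 1072 among the brighter probe sets, 680 with a mean above 6, 4349 with weights, 167 with the minimum change, 2923 in the fit to 6 arrays, 946 without replicate 1 and 38 without replicates 2 and 3. It ranged from 663 (without 12 h replicate 2) to 2211, and was 938 and 698 without 3 h replicates 2 and 3 and 805 without 12 h replicate 3. The F test count was 5261 and 2044 with fewer probe sets, 6272 with the floor and 4630 without infected replicates 2 and 3, and 10647 to 11154 with single arrays left out.

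The replicate numbers were not taken to pair the arrays, since the labels do not say that they do and 5 of 12 arrays correlated best with their own number. The infected replicate 1 arrays did vary together: their deviations correlated at 0.217 to 0.294, against 0.025 to 0.102 for infected replicate 2, 0.050 to 0.066 for replicate 3 and -0.030 to 0.055 for same numbers with 0 h. With the replicate block the counts were 11178, 11353, 9308, 90, 921 and 1294 for the 6 contrasts in the order of the report, against 11254, 11430, 9500, 99, 1274 and 1646.

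Of 60 list tests 22 passed, against 12 with an estimated correlation, 45 with fry, 8 after quantile normalization, 13 among the brighter probe sets, 9 with a mean above 6 and 11 after cyclic loess. Calls shared by 2 times and at least 2-fold were 1617 up and 2368 down for 3 h and 6 h, 905 and 1961 for 3 h and 12 h, and 949 and 1996 for 6 h and 12 h.

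Some results turned direction. HisK-2 at 6 h had a change of 0.090 and 7TMS-4 at 6 h one of -0.024 after quantile normalization, neither passing. 7TMS-5 had -0.19 after median centring and -0.25 after cyclic loess at 3 h, and -0.20 and -0.25 at 6 h, all passing. The Avr1b-1 difference at 3 h, -0.64 and not passing, was 0.058 after quantile normalization and 0.20 after cyclic loess, also not passing. Fry tests movement on balance and camera sets a list against the other probe sets, and for 14 list tests they pointed opposite ways, fry passing each time. The medians there were, for psHA, -0.11, -0.25 and -0.063 at 3, 6 and 12 h against 0 h and -0.11 for 12 h against 3 h. For psHB they were 0.10, 0.12 and 0.051 against 0 h and -0.12 and -0.11 for 12 h against 6 h and 3 h. For 12 h against 6 h and 3 h they were -0.097 and -0.12 for psMA and -0.087 and -0.091 for psMY, and psZO had -0.11 against 3 h. With a mean above 6, camera turned and passed for psHA at 3 h and 6 h (medians -0.39 and -0.46), for psHB at 3, 6 and 12 h (-0.32, -0.33 and -0.18), and at 12 h against 6 h and 3 h for psHB (0.014 and 0.0101). It turned without passing for psZG at 3 h and 6 h (-0.41 and -0.37, adjusted p = 0.486 and 0.577), for psMA at 6 h (-0.64, adjusted p = 0.759) and for psMC at 12 h against 6 h (0.24, adjusted p = 0.876). Of the other values of named probe sets and lists under alternatives, 2963 and 367 stayed on the same side of the threshold, 164 and 64 no longer passed, and 27 and 18 newly passed. Of the 2963, 105 log2 changes took the other sign, all where neither value passed. Camera kept its direction or passed neither time in the 367, but the list median took the other sign in 61 that did not pass and 4 that did, and in 16 of the 64 and 2 of the 18.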

Other observations

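The tests of the fall of bright probe sets and of the early risers were chosen after those results were seen, and those of neighbouring probe set numbers before. Probe sets were also grouped by when they rose, with limits set after the data had been seen. There were 30 early risers, with a 0 h mean under 5 that rose by more than 4 log2 units at 3 h. Their median was 3.39 at 0 h, 10.3 at 3 h, 9.68 at 6 h and 8.76 at 12 h. The prefixes psHA and psHB held 93.3% of them. There were 111 late risers, which rose by more than 2 log2 units from 3 h to 12 h. Their median was 5.65 at 0 h, 5.55 at 3 h, 6.80 at 6 h and 8.90 at 12 h. Of these 80 were C probe sets, 23 CL probe sets and 4 psHA or psHB probe sets.

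The early risers came mostly from 2 ID prefixes. psHA and psHB held 28 of the 30, or 93.3%, against 3.65% of all probe sets (odds ratio 384, with a lower 95% bound of 97.2; Fisher's exact test, two-sided p = 1.22e-38), and 0 were C probe sets. A candidate explanation is that these probe sets read soybean transcripts, whose share would fall as the pathogen grows: of 32 chosen on 3 h replicate 1 alone, 31 were lower at 12 h than in 3 h replicates 2 and 3, with a median of -1.19, against 74.3% of all probe sets and a median of 0.35 in the brightest 10%. *P. sojae* genes switched on by 3 h and then declining stay open: the share of C probe sets was lower by 72.1 percentage points among early than late risers, which goes against them, but C made up 7.05% of the other probe sets as bright at 3 h, against 77.5% of all, so the gap does not decide. The 1 row with a soybean ID prefix read 12.0 in mycelium without plant tissue, so an ID prefix alone does not settle which transcript is read, and no soybean probe sets were analysed here beyond it.

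Bright probe sets were lower in all 9 infected arrays than in mycelium. The median of the brightest 10% lay below the 0 h mean by log2 differences of -0.76 to -0.69 at 3 h, -0.91 to -0.58 at 6 h and -0.42 to -0.20 at 12 h. Loss of RNA 5′ ends in infected replicates 2 and 3 is argued against as the cause, because the fall in infected replicate 1, whose actin signal was like that of mycelium, was 1.09, 1.25 and 1.84 times that of the other replicates at 3, 6 and 12 h. Dilution of *P. sojae* RNA by plant RNA may be a source: the fall was smaller at 12 h than at 3 h by 0.43 on the log2 scale, beyond the range of the arrays. A growing share of pathogen RNA would give this. Some other values may not go with dilution alone. The bright 3′ actin control did not fall, with means of 12.84 at 0 h and 13.05, 12.97 and 13.35 at 3, 6 and 12 h. This is 1 row. The other actin rows had log2 changes at 3 h of -0.89 (middle) and of -1.33 and -2.12 (5′), none passing by limma. On 3 h replicate 1, where the 5′ signal was like that of mycelium, the middle and 5′ rows read 13.46 and 11.36, above all 0 h arrays. The dimmest 10% rose at 3 h, with a median of 0.30, which normalization between arrays of unlike RNA mixture could also give. That was not tested. The fall of the brightest 10% at 6 h (median -0.82) could not be told from that at 3 h (-0.76), since the 6 h arrays spanned the 3 h range. Lower transcript levels in infected tissue remain open and were not tested apart from dilution, since mycelium and infected tissue differ in both.

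Probe sets named C with consecutive numbers changed alike between 3 h and 12 h. IDs that end in _s_at, used for probe sets that match several transcripts, were left out. Over 7586 such pairs the correlation of log2 changes across probe sets was 0.195 (Spearman's rho 0.165), with a permutation p of 1e-04, the smallest that 10000 permutations can give. It was 0.041 for numbers 2 apart and 0.013 for numbers 3 apart, and among the 161 at least 2-fold higher at 12 h, of 202 C probe sets in all, there were 11 consecutive pairs, against 1.54 on average and at most 8 in permutations. A shared dependence on signal level is argued against, since 0.162 remained after the trend with level was removed. The correlation was 0.203 in the 7267 pairs left without the numbers that also have an _s_at probe set. This argues against those numbers as the source. Whether neighbouring probe sets without that ending read the same or similar transcripts was not tested. What consecutive numbers mean is not given in the sources used here, and no biological explanation was tested.

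Dim probe sets read nearly the same on the 3 h and 6 h arrays. Below the median of mean level, 58.6% had a range under 0.2 over the 6 arrays at 3 h and 6 h, against 4.36% in the brightest 10%, and 3 of the 13 effectors did. The median SD of those below the median level was 0.16 at 0 h, 0.046 at 3 h and 0.056 at 12 h. Pairs of infected arrays from different times shared at most 265 identical values, pairs of 0 h arrays at most 20, and a 0 h array and an infected one at most 3.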
